A study of Arabidopsis thaliana with 6 samples.

How the data were processed

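Gene expression was measured on 6 Affymetrix ATH1 arrays, 2 for each of 3 groups of whole Arabidopsis thaliana seedlings: empty-vector control, prolonged induction and temporal induction. The deposited values are intensity signals on a linear scale, 1 per probe set and array, made with MAS5 in GCOS per the submitters' processing notes, whose versions are not given in the sources used here. On every array the mean signal after trimming 2% from each end was 100.01, so the arrays had been scaled to a common level before they were deposited. Detection calls and image files were not analysed here. Labelling used the one-cycle protocol per the labels. Median signal was 53.1 to 58.8 per array, and the number of arrays per group, 2, limits precision: the median standard error of a log2 fold change was 0.32.

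The table held 22810 probe sets. The 64 Affymetrix control probe sets were kept out of the tests and read only for RNA quality and array scale. Of the other 22746, 13513 carried 1 gene symbol, 503 several and 8730 none in the table of probe names used here, and 13436 of those with 1 symbol matched a gene of the TAIR10.1 annotation, which served only for names and the order of neighbouring genes. Probe sets with several symbols were tested but no gene was named from them. Where a gene had several tested probe sets, as 80 genes did, the one with the highest mean signal stood for it.

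Signals were taken to log2, the 30% of probe sets with the lowest mean were left out, and the remaining 15922 were fitted with limma 3.58.1 in R 4.3.3 on all 6 arrays (3 residual degrees of freedom, 7.96 prior degrees of freedom, variance prior with an intensity trend). The 3 comparisons were prolonged induction against control, temporal induction against control, and prolonged against temporal induction. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05. With 2 arrays against 2 an exact rank test cannot give a two-sided p below 0.333, so the tests rest on the pooled variance. Fold changes are given on the log2 scale with the standard error of the fit, signals as mean ± SD of 2 arrays.

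The genes named were set by a rule written before the data were examined: per comparison, among probe sets with 1 symbol that passed and in which both arrays of one group lay above both of the other, the 10 largest rises and 10 largest falls, every measured chloroplast division gene, and up to 4 members with the smallest p of each list described. In all, 26 lists were fixed at the same time. Of these, 24 held 388 distinct nuclear genes, of which 47 were tested, and the other 2 were the genes of the plastid and mitochondrial genomes, of which 69 and 8 were tested. Lists with at least 5 tested members, 4 of the 26, were tested as sets with camera in limma at a preset correlation between genes of 0.01 and again with the correlation estimated per list. A further 7 lists, 34 families of genes with a common symbol stem, and a division of the plastid genome list were chosen after the leading genes were seen, and each kind was adjusted on its own. Single members were adjusted over all tested probe sets and also over their list alone.

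The responses to the 2 inductions were compared by their overlap, correlation and covariance. Since both use the same controls, 100 data sets with unchanged groups were simulated to give the values that the shared controls produce by themselves, and covariance and correlation were also computed with each response against a different control array.

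Alternatives tried were quantile normalization, median centring and cyclic loess, log2 of the signal plus 25.9, no filter, the lowest 50% left out, no intensity trend, a fit of only the 2 groups compared, the replicate number as a block, and each array left out in turn. The scripts were tested on simulated data of 15922 probe sets, of which 200 were changed, 100 by 1 and 100 by 2 log2 units. In the simulated comparison of prolonged induction with control, 32% and 67% of these were found, and 4 of 103 calls were false. In that of temporal induction with control 32% and 71% were found with 3 of 106 false, and in that of the induced groups 37% and 70% with 14 of 121 false. A simulated list of 60 genes shifted by −0.4 passed in all 3 comparisons and an unchanged list in none. The simulated genes varied independently, so this does not show how the list test behaves when genes of a list vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.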

Results

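Transcript levels were measured in whole 14-day-old Arabidopsis thaliana seedlings of Landsberg background with 4 rosette leaves, grown in constant light. The study concerned nuclear gene expression when division of chloroplasts is inhibited, and the inhibiting transgene is not named in the sources used here. Each of 3 groups had 2 ATH1 arrays, Affymetrix oligonucleotide arrays with several probes per transcript. Control seedlings carried the empty inducible vector PER-10 and were sprayed with 2 µM estradiol, the inducer, at day 13, 24 h before harvest. Temporal induction seedlings received a single spray at the same age. The labels write 17-B-estradiol for the controls and 7-B-estradiol for the induced groups, which was read here as the same compound. Prolonged induction seedlings were sown on inducer and sprayed every 24 h until harvest. The labels give the background of the controls as Ler-0 and of both induced groups as Ler-1. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

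All 6 arrays had a trimmed mean signal of 100.01, and their median signals ran from 53.1 to 58.8. The ratio of 3' to 5' control probe sets, a sign of RNA integrity, was 1.82 to 2.67 for GAPDH, 3.19 to 6.14 for actin and 1.58 to 1.87 for ubiquitin. For actin it was 4.19 in both control arrays, 6.14 and 4.45 after prolonged induction, and 3.19 and 5.22 after temporal induction. The actin ratio was thus higher in both prolonged arrays than in both control arrays, whereas those of GAPDH and ubiquitin overlapped between these groups. The 25S ribosomal RNA probe set read 2701 and 4532 in the control arrays, 1026 and 1674 after prolonged induction, and 2994 and 1222 after temporal induction. Across probe sets, log2 signals of the pairs within a group correlated at r = 0.881 (control), 0.894 (prolonged) and 0.914 (temporal). Between control and prolonged induction r was 0.834 to 0.845, between control and temporal induction 0.863 to 0.867, and between the induced groups 0.895 to 0.914. These are correlations across probe sets, which are not independent replicates. The number of arrays limits the precision of every value below.

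The comparison of prolonged induction with control asked how transcript levels differ in seedlings kept on inducer from sowing. AT4G12500, a lipid transfer protein family gene, rose from a signal of 22.4 ± 3.86 to 497 ± 141 (SD, n = 2 arrays each; log2 fold change 4.46 ± 0.28 SE, adjusted p = 1.15e-05). AT5G64120, which encodes a class III peroxidase, rose from 41.9 ± 40.6 to 793 ± 138 (log2 fold change 4.69 ± 0.56). Its 2 control arrays read 13.2 and 70.7, and its log2 fold change was 3.48 without the first and 5.90 without the second, so its size is not exact. The chitinase family gene AT2G43620 rose from 72.2 ± 29.5 to 971 ± 36.0, and AT5G22430, of the pollen Ole e 1 family, from 13.4 ± 8.44 to 287 ± 39.5. GSTU25 (AT1G17180), a tau class glutathione transferase gene, fell from 320.1 ± 84.6 to 19.4 ± 7.87 (log2 fold change −4.08 ± 0.33 SE, adjusted p = 5.56e-05). Signals under 23.5, as of AT4G12500 and AT5G22430 in control and of GSTU25 after prolonged induction, lie in the range of the probe sets left out as low, so fold changes to or from them are not exact.

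In all, 1107 of 15922 tested probe sets passed an adjusted p of 0.05 in limma. Of these, 600 rose and 507 fell, and 547 changed over 2-fold. Falls outnumbered rises when prolonged replicate 1 was left out, so this balance is not firm. Both arrays of one group lay above both of the other for 47.7% of the tested probe sets, where chance gives 33.3%. Among the 492 passing probe sets with 1 gene symbol, the other leading rises were the lipid transfer family gene AT1G66850 (log2 fold change 5.16 ± 1.15), AT1G68875 (4.37 ± 0.67), the anther β-glucosidase gene ATA27 (AT1G75940; 3.50 ± 0.70), AT4G23680 of the major latex protein family (3.47 ± 0.57), the wax ester synthase gene WSD1 (AT5G37300; 3.35 ± 0.81) and AT2G36690 (3.33 ± 0.51). The 2 control arrays read 2.40 and 88.9 for AT1G66850. Leading falls included AT3G61400 (−2.86 ± 0.77), AT3G15650 (−2.64 ± 0.60), the extensin-like gene AT3G28550 (−2.58 ± 0.53), AT5G14650 of the pectin lyase-like family (−2.40 ± 0.47), AT5G57070 (−2.31 ± 0.46) and the copper amine oxidase gene AT1G31690 (−2.30 ± 0.50). AT5G32410 (−2.20 ± 0.52), AT3G44370 (−2.18 ± 0.57) and AT4G33720, of a pathogenesis-related protein family (−2.13 ± 0.29), completed the 10. Among probe sets without a symbol, the 2 largest rises were from 7.58 ± 4.50 to 1875 ± 113 and from 9.69 ± 7.21 to 448 ± 84.5. The order of these rises and falls is not exact either, since many have a group mean under 23.5, such as AT3G61400 (7.19), AT3G15650 (13.0) and AT5G14650 (19.3) after prolonged induction.

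Median centring gave 856 calls, no filter 880, the fit of 2 groups 812, quantile normalization 1088 and the replicate block 1046. Cyclic loess gave 1120, the offset 1201 and leaving out the lowest 50% 1194. The number of calls also fell without the intensity trend and when any 1 array was left out. A temporal array does not enter this fold change, so omitting it changes only the estimate of the spread. Losses without 1 array therefore need not come from the values of that array. The count was 772 without control replicate 1, 897 without control replicate 2, 633 and 726 without prolonged replicates 1 and 2, 780 and 779 without temporal replicates 1 and 2, and 47 without the intensity trend. Of the 10 leading rises, AT1G66850, AT4G23680, ATA27 and WSD1 did not pass without prolonged replicate 1 (adjusted p up to 0.189). AT1G66850, AT1G68875, AT2G36690, ATA27 and WSD1 did not pass without prolonged replicate 2 (up to 0.155), and WSD1 did not without either temporal array (0.0667 and 0.0659). All 10 passed without either control array. Of the 10 leading falls, AT3G44370 and AT3G61400 did not pass without any one of the 6 arrays, and AT5G32410 passed only without prolonged replicate 2 among these 6 omissions. AT3G15650 failed without either control array, prolonged replicate 2 or temporal replicate 2, AT3G28550 without control replicate 1 or prolonged replicate 1, and AT1G31690 without control replicate 2 or prolonged replicate 1. AT5G14650 failed without control replicate 1 and AT5G57070 without prolonged replicate 1. The highest adjusted p among the falls was 0.221 without control replicate 1, 0.230 without control replicate 2, 0.110 and 0.0921 without prolonged replicates 1 and 2, and 0.123 and 0.109 without temporal replicates 1 and 2. GSTU25 and AT4G33720 passed in all 6. AT3G61400 also failed after quantile normalization (0.0549), median centring (0.0582) and with an offset added before the logarithm (0.0536). Without the intensity trend 3 of the 10 rises and 1 of the 10 falls, that of GSTU25, passed.

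Among photosynthesis genes, single genes fell after prolonged induction. All 3 measured Calvin cycle genes fell: PRK (AT1G32060, phosphoribulokinase) from 3161 ± 242 to 1864 ± 248, SBPASE (AT3G55800, sedoheptulose bisphosphatase) from 2043 ± 415 to 1069 ± 214, and RCA (AT2G39730, Rubisco activase) by 0.53 on the log2 scale (adjusted p = 0.0443). Of 3 measured antenna genes, LHCB4.3 (AT2G40100) fell from 583 ± 44.3 to 298 ± 24.5 and 2 did not pass (2 fell adjusted over the list alone). The chlorophyll-pathway gene HEME2 (AT2G40490, log2 fold change −0.73 ± 0.19) and LIL3:1 (AT4G17600, −0.75 ± 0.17) fell, as did DFR (AT5G42800), an anthocyanin synthesis gene, by 1.79 on the log2 scale.

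As a set, 5 measured photosystem and electron carrier genes had a median log2 fold change of −0.39 (camera adjusted p = 0.00528; adjusted p = 0.20 with an estimated correlation). None of the 5 passed on its own in limma, 4 fell adjusted over the list alone, and 4 had an unadjusted p under 0.05. The shift did not pass after quantile normalization (adjusted p = 0.0952) or cyclic loess (0.0689), nor without prolonged replicate 2 (0.0613). For tetrapyrrole synthesis, 1 of 7 measured genes, HEME2, fell and the median was −0.40 (adjusted p = 0.00859; adjusted p = 0.147 with an estimated correlation), with 1 fall adjusted over the list alone. Without prolonged replicate 2 it did not pass (0.0578). RCA did not pass after quantile normalization, median centring or cyclic loess (adjusted p = 0.107, 0.216 and 0.188), nor without control replicate 1, prolonged replicate 2 or either temporal array, SBPASE not without prolonged replicate 2, HEME2 not without any of the control or prolonged arrays, and LIL3:1 not without either control array or prolonged replicate 2. HEME2 and LIL3:1 also failed after median centring (0.0792 and 0.0568). Few members of the fixed lists of nuclear genes could be measured, 47 of 388 distinct genes, since the table of probe names used here leaves many probe sets unnamed.

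Of 69 measured plastid genome genes, 7 fell after prolonged induction. rpoC2, an RNA polymerase subunit gene, went from 1332 ± 134 to 522 ± 67.0 and rps15, for a ribosomal protein, from 1474 ± 49.97 to 648 ± 56.8. rps2, rpoA, rpoC1 and rpl16 fell by 0.80 to 0.90 on the log2 scale, and petA, for cytochrome f, by 0.56. The other 62 did not pass. Adjusted over the list alone 5 rose and 12 fell, and the median over all 69 was −0.21 (camera adjusted p = 0.00434; adjusted p = 0.551 with an estimated correlation). Without control replicate 1 the median was 0.01 and the test turned to a rise, and the shift did not pass after quantile normalization (0.137), cyclic loess (0.250) or without prolonged replicate 2 (0.186). A split made after the members were seen put 20 transcription and translation genes at a median of −0.53 and the 49 others at 0.07. Without control replicate 1 these medians were −0.48 and 0.46, and without control replicate 2 −0.64 and −0.42, so the direction of the 49 rested on which control array was used. The 20 include 6 of the 7 genes that passed, and the other 14 had a median of −0.42. The split was chosen on the same values, those of the 14 included, so it is no separate test. rpoC1 did not pass without prolonged replicate 2, and petA not without control replicate 2, prolonged replicate 2 or either temporal array, nor after quantile normalization or median centring.

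Of 8 measured mitochondrial genome genes, 2 rose after prolonged induction. cox1, for cytochrome oxidase subunit 1, rose from 239.5 ± 1.75 to 398 ± 71.6 and nad4L, for a complex I subunit, from 60.4 ± 8.97 to 145 ± 34.9. Adjusted over the list alone 4 rose, and the median of the 8 was 0.61 (adjusted p = 0.00268; adjusted p = 0.147 with an estimated correlation). cox1 did not pass after median centring (0.0535) or without either control array, prolonged replicate 1 or either temporal array, and nad4L not without control replicate 2 or prolonged replicate 1. One-cycle labelling primes on poly(A) tails and some mitochondrial genes have near-identical nuclear copies, so signals of plastid and mitochondrial genes need not follow organelle transcript levels. Nuclear genes for ribosomal proteins were tested in lists written after the leading genes were seen. Of 9 measured genes for plastid ribosomal proteins 8 fell, AT1G29070 from 1077 ± 14.3 to 433 ± 48.4, with a median of −0.85 (adjusted p = 4.10e-11; adjusted p = 0.0542 with an estimated correlation). Of 104 genes for cytosolic ribosomal proteins 33 fell and 0 rose, AT5G61170 from 1334 ± 47.8 to 752 ± 43.8, with a median of −0.44 (adjusted p = 1.59e-17; adjusted p = 0.0339 with an estimated correlation). Of these 104, 57 had an unadjusted p under 0.05. The 25S ribosomal RNA signal was lower in both prolonged arrays than in both control arrays, but the 2 temporal arrays read 2994 and 1222. With labelling from poly(A) tails it need not follow the level of ribosomal RNA.

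Of 21 chloroplast division genes, 3 were measured. FTSZ2-1 (AT2G36250) and FTSZ2-2 (AT3G52750), which encode proteins of the plastid division ring, had log2 fold changes of 0.03 ± 0.20 and −0.95 ± 0.58, and FZL (AT1G03160) one of −0.27 ± 0.26. In limma 0 passed, adjusted over the list alone also 0, and 0 had an unadjusted p under 0.05. The sign of FTSZ2-1 turned after quantile normalization (−0.00131), after cyclic loess (−0.000806), and without control replicate 2 (−0.14) or prolonged replicate 2 (−0.07). Root markers were measured because whole seedlings hold root. EXPA7 (AT1G12560) and EXPA18 (AT1G62980), expressed in root hair cells, had log2 fold changes of −1.36 ± 0.42 and −1.93 ± 0.54, and PYK10 (AT3G09260), an abundant root β-glucosidase gene, read 4333 ± 462 in control and 3219 ± 850 after prolonged induction. None of these 3 passed (3 fell adjusted over the list alone, and 3 had an unadjusted p under 0.05), although without prolonged replicate 1 EXPA18 (log2 fold change −2.46) and PYK10 (−0.72) did. The only measured gene of the flowering list, AGL24 (AT4G24540), had a log2 fold change of 1.45 and did not pass (adjusted p = 0.0860).

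**Figure D1:**
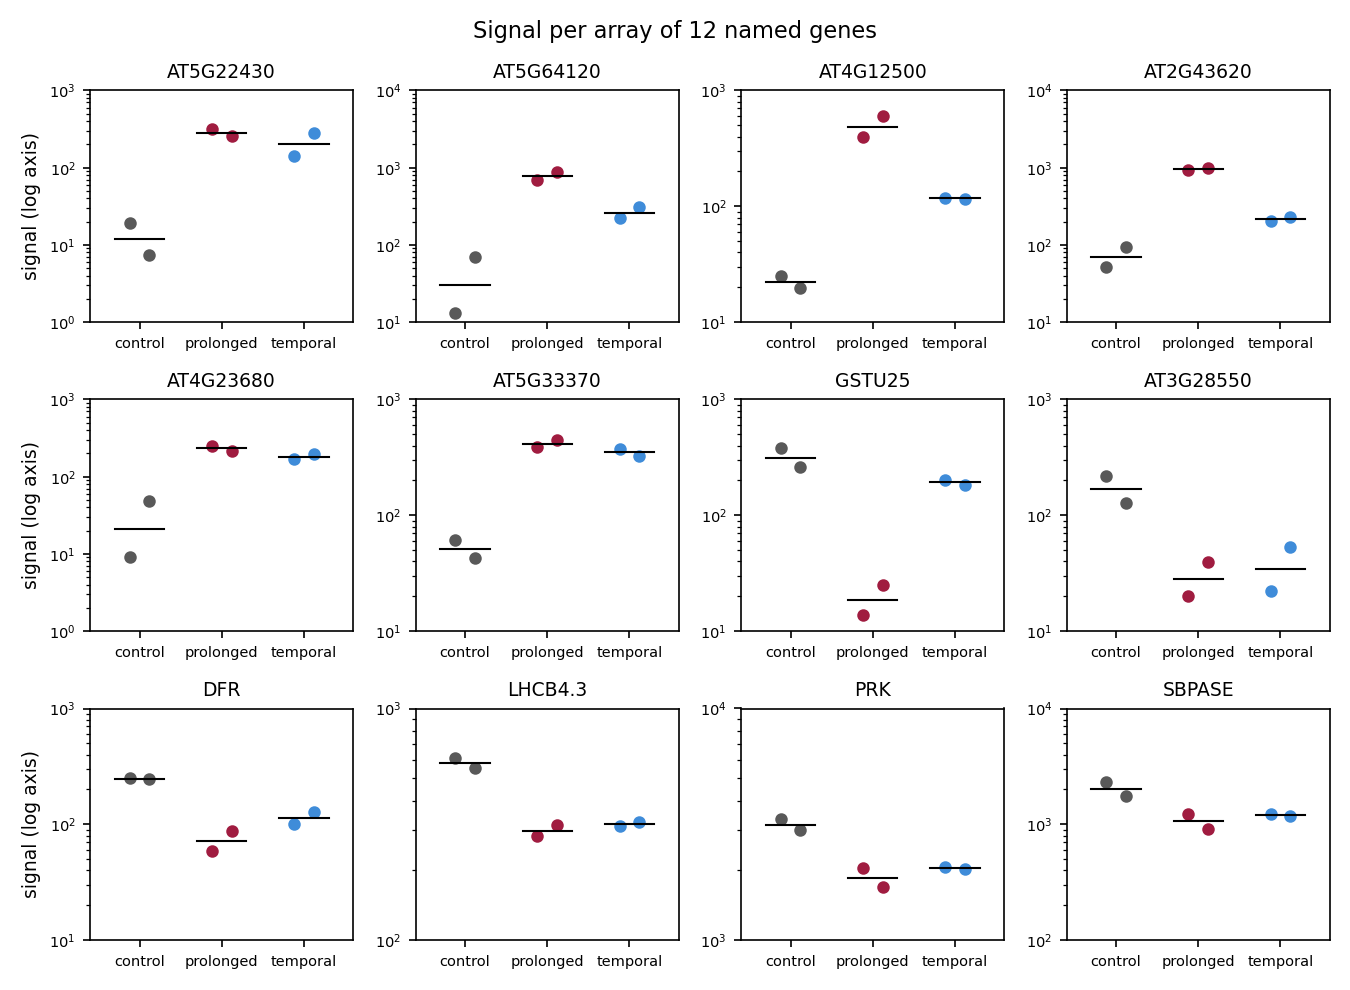
Signal of 12 named genes on each array (points, logarithmic axis) with the mean of the log2 values of each group as a line; n = 2 arrays per group. GSTU25 read 13.9 and 24.99 after prolonged induction against 379.9 and 260.2 in control, while AT5G22430 was high in both induced groups.

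Temporal induction was set against a control that received the same single spray, to find transcripts that differed 24 h after the inducer. Induced-line seedlings without inducer were not among the groups. A constant difference between the lines would therefore look the same as a response. AT5G22430 rose from 13.4 ± 8.44 to 213 ± 101 (SD, n = 2 arrays each; log2 fold change 4.07 ± 0.46 SE, adjusted p = 0.00135). The GDSL lipase family gene AT5G33370 rose from 52.2 ± 13.6 to 351 ± 32.1, the lipid transfer family gene AT5G62080 from 11.9 ± 0.950 to 118 ± 9.73, and AT5G64120 from 41.9 ± 40.6 to 266 ± 59.9. AT1G35280 fell from 107 ± 8.28 to 16.4 ± 2.37 (log2 fold change −2.71 ± 0.35, adjusted p = 0.00297), on a probe set of a kind that can match several similar transcripts. AT3G28550 fell from 174 ± 63.8 to 37.6 ± 21.7 and the pectate lyase gene AT5G63180 from 391 ± 13.1 to 168 ± 25.2. The control signals of AT5G22430 and AT5G62080 and the temporal signal of AT1G35280 lie under 23.5, so their fold changes are not exact.

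The test passed 386 probe sets, of which 270 rose and 116 fell, and 167 of them had 1 gene symbol. Both arrays of one group lay above both of the other for 46.3% of the tested probe sets, where chance gives 33.3%. Further leading rises were AT1G68875 (log2 fold change 4.00 ± 0.67), AT5G64180 (3.29 ± 0.67), the GDSL lipase family gene AT2G42990 (3.18 ± 0.68), AT4G23680 (3.12 ± 0.57), the dihydroxyacetone kinase gene AT1G48430 (3.03 ± 0.43) and AT5G19580 (2.49 ± 0.51), of the glyoxal oxidase family. All but AT4G23680 had control means under 23.5 (8.11, 7.44, 11.4, 12.1 and 13.3), and the control arrays of AT4G23680 read 9.15 and 48.1, so these fold changes and their order are not exact. Further falls were AT3G24250, AT2G10930, AT4G29560, AT5G35660, AT1G07310, AT5G11980 and AT2G01440, with log2 fold changes from −1.59 to −1.20. The 2 probe sets without a symbol that rose most after prolonged induction rose here too, by log2 fold changes of 6.98 and 5.49. After median centring 249 probe sets passed, 71 without temporal replicate 1 and 56 without temporal replicate 2. In limma without the intensity trend 0 passed, where 1874 had an unadjusted p under 0.05. Without either temporal array AT5G22430 and AT5G33370 were the only 2 of the 10 leading rises that passed (others up to 0.262 and 0.267). AT2G42990, AT4G23680, AT5G19580 and AT5G64120 also failed without either prolonged array, and AT5G64180 without prolonged replicate 1 (up to 0.0865).

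Of the 10 leading falls, AT1G35280 alone passed without temporal replicate 1 (adjusted p of the others up to 0.295), and AT1G35280, AT5G63180 and AT5G11980 passed without temporal replicate 2 (others up to 0.236). Without control replicate 1 AT1G07310, AT1G35280 and AT5G63180 passed (others up to 0.249), and without control replicate 2 AT1G35280, AT4G29560, AT5G35660 and AT5G63180 did (others up to 0.148). AT2G10930, AT3G28550, AT4G29560 and AT5G11980 failed without either prolonged array (up to 0.0809 and 0.0819). With no filter on low signals AT1G35280, AT3G24250, AT5G35660 and AT5G63180 passed (others up to 0.0857), and AT5G11980 failed after quantile normalization or median centring.

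Some of the same photosynthesis genes fell after the single spray. PRK fell to 2049 ± 36.3, SBPASE to 1195 ± 29.6 and LHCB4.3 to 318 ± 7.45, while RCA did not pass (log2 fold change −0.28 ± 0.14, adjusted p = 0.391). ATPC1 (AT4G04640), for the γ subunit of the chloroplast ATP synthase, fell by 0.63 on the log2 scale, the single passing gene of 5 in the photosystem and electron carrier list, also adjusted over the list alone (1 fell). That list had a median of −0.20 (adjusted p = 0.0123; adjusted p = 0.219 with an estimated correlation) and did not pass after quantile normalization (0.0941) or cyclic loess (0.0634), without the intensity trend (0.0923) or without temporal replicate 1 (0.111). DFR fell by 1.13. PRK, SBPASE and ATPC1 did not pass under quantile normalization or median centring, nor, with LHCB4.3 and DFR, without control replicate 1 or without either temporal array. ATPC1 and DFR also failed without control replicate 2. For tetrapyrrole synthesis 0 of 7 genes passed in limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, with a median of −0.26 (adjusted p = 0.0504; adjusted p = 0.219 with an estimated correlation). With no filter on low signals that list passed (0.0393).

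In the plastid genome rpoC2 fell to 713 ± 39.3 and rps15 to 816 ± 53.7, and rps2 and rpoA fell as well, 4 of 69 genes (1 rose and 6 fell adjusted over the list alone). After median centring rps2 and rpoA did not pass, while rpoC2 and rps15 did. The median over all 69 was −0.08 (adjusted p = 0.0335; adjusted p = 0.658 with an estimated correlation). It was 0.16 without control replicate 1, where the test turned to a rise (adjusted p = 0.000167), and the shift did not pass after quantile normalization (0.562), cyclic loess (0.359) or median centring (0.0526), nor without temporal replicate 1 (0.0695) or 2 (0.0595). All 4 genes failed without either temporal array, rps2 also without control replicate 1 and rpoA without control replicate 2. In the split made after the members were seen, the 20 transcription and translation genes had a median of −0.40 and the 49 others 0.03. The 14 of the 20 that had not passed after prolonged induction had one of −0.29. Without control replicate 1 the medians of the 20 and the 49 were −0.26 and 0.45, and without control replicate 2 −0.59 and −0.35. The direction of the 49 thus rested on which control array was used. The 8 mitochondrial genes had a median of 0.35 (adjusted p = 0.0117; adjusted p = 0.217 with an estimated correlation). In limma 0 of the 8 passed, 0 adjusted over the list alone, and 2 had an unadjusted p under 0.05. Of the nuclear genes for plastid ribosomal proteins 1 of 9 fell, AT4G01310 (log2 fold change −0.62), with a median of −0.48 (adjusted p = 1.69e-06; adjusted p = 0.0976 with an estimated correlation). Of those for cytosolic ribosomal proteins 7 of 104 fell, with a median of −0.28 (adjusted p = 1.71e-12; adjusted p = 0.0563 with an estimated correlation). AT4G01310 did not pass after median centring or without either control or either temporal array.

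Among division genes FTSZ2-2 read 146 ± 37.9 in control and 56.4 ± 50.04 after temporal induction (log2 fold change −1.71 ± 0.58, adjusted p = 0.182). FTSZ2-1 and FZL had log2 fold changes of −0.06 and −0.36. In limma 0 of 3 passed, 1 had an unadjusted p under 0.05, and 1 fell adjusted over the list alone. Without temporal replicate 2 FTSZ2-2 passed, with a log2 fold change of −2.77. Without control replicate 1 or temporal replicate 1 that of FTSZ2-1 was 0.11 or 0.02. The root markers EXPA7, EXPA18 and PYK10 had log2 fold changes of −0.99, −0.15 and −0.25 (0 passed, 0 fell adjusted over the list alone, 1 had an unadjusted p under 0.05).

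**Figure D2:**
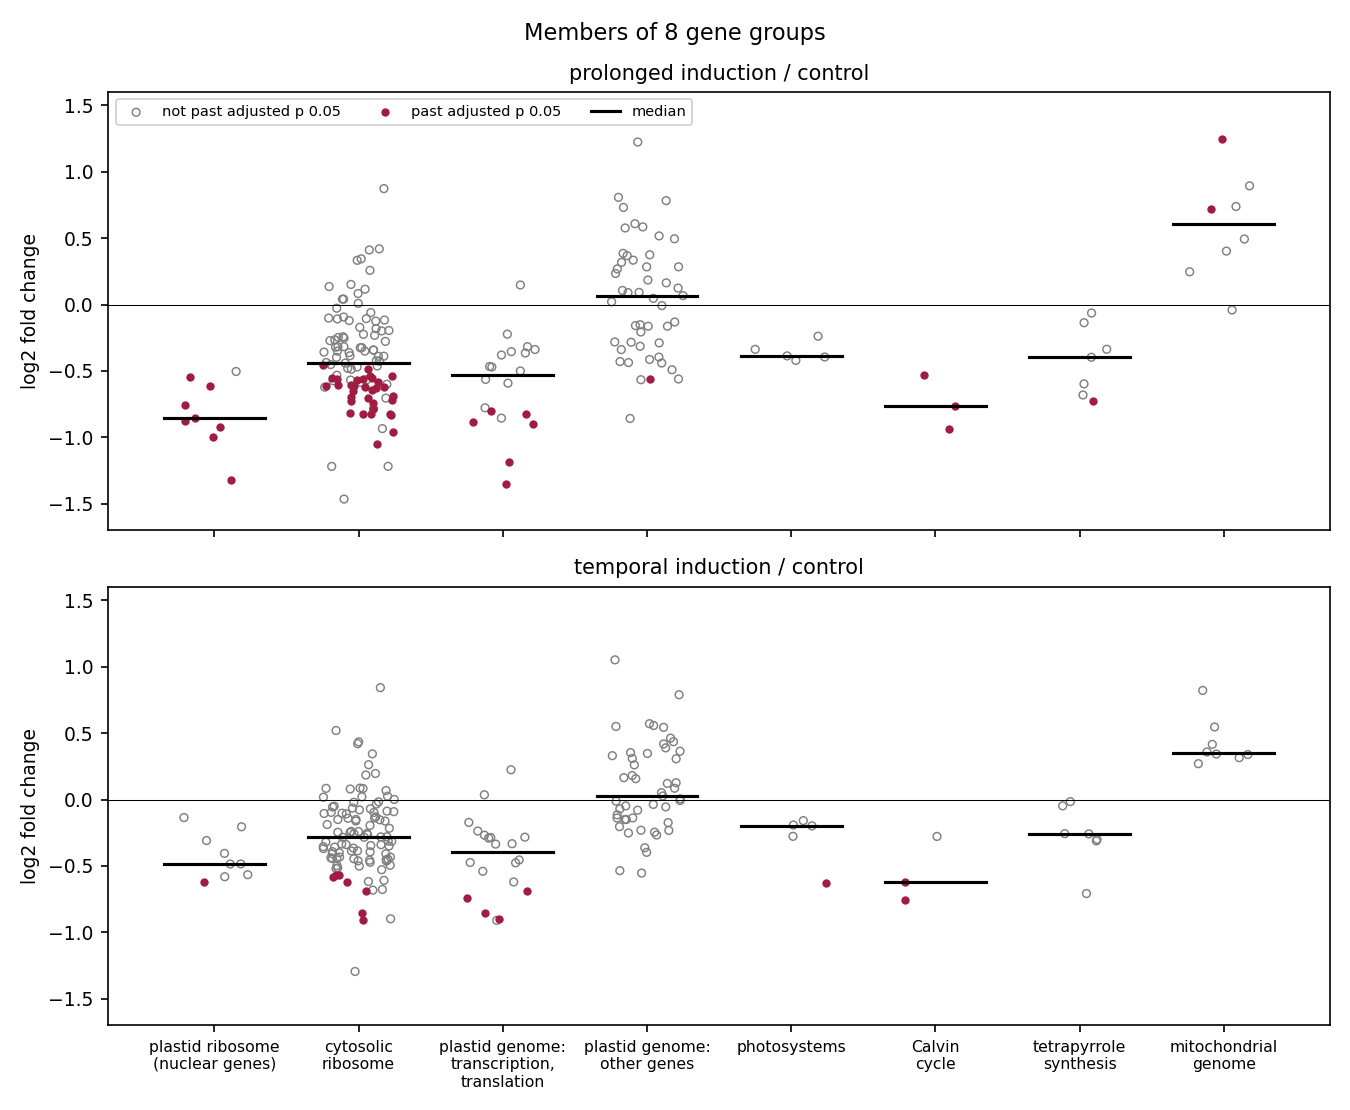
Log2 fold changes of the members of 8 gene groups against control after prolonged (top) and temporal (bottom) induction; filled points passed an adjusted p of 0.05, lines are medians, and each fold change compares 2 arrays with 2. The medians of nuclear genes for plastid ribosomal proteins were −0.85 and −0.48, and those of mitochondrial genes 0.61 and 0.35.

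Prolonged and temporal induction were compared directly to find transcripts that differed between these 2 treatments. The treatments differ in the length and route of exposure to estradiol and in the number of sprays. No empty-vector group received the prolonged treatment, so effects of estradiol or spraying themselves were not separated. GSTU25 was lower after prolonged induction, at 19.4 ± 7.87 against 193 ± 15.0 (SD, n = 2 arrays each; log2 fold change −3.37 ± 0.33 SE, adjusted p = 0.00368). AT4G33720 (45.9 ± 16.6 against 215 ± 43.7, log2 fold change −2.26) and the osmotin gene OSM34 (AT4G11650; 147 ± 73.2 against 602 ± 83.4) were lower too. The lipid transfer family genes AT4G12490, at 1984 ± 63.0 against 530 ± 33.3 (adjusted p = 0.000284), and AT4G12500 were higher, as were AT2G43620 (971 ± 36.0 against 218 ± 17.5) and AT1G35280 (122 ± 3.06 against 16.4 ± 2.37). The lower signals of GSTU25 and AT1G35280 lie under 23.5, so their differences are not exact.

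In this comparison 14 probe sets passed, 6 higher and 8 lower, 7 of them with 1 symbol, and 940 had an unadjusted p under 0.05. The groups lay apart for 34.9% of the tested probe sets, where chance gives 33.3%. Of the 4 fixed lists with enough members 0 passed in camera, and 1 had an unadjusted p under 0.05. The 3 division genes had log2 fold changes of 0.08 to 0.76 and 0 passed in limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Without either temporal array 1 probe set passed, that of AT4G12490, and the others named had adjusted p up to 0.364. Without prolonged replicate 1, 11 passed, and AT1G35280, AT2G43620, AT4G12500 and AT4G33720 did not (up to 0.159). Without prolonged replicate 2, 6 passed, and AT1G35280, AT2G43620, AT4G12500 and OSM34 did not (up to 0.290). None passed without the intensity trend, where 812 had an unadjusted p under 0.05. The nuclear genes for plastid ribosomal proteins had a median of −0.34 (adjusted p = 3.25e-09; adjusted p = 0.0580 with an estimated correlation) and those for cytosolic ribosomal proteins one of −0.13 (adjusted p = 2.39e-06; adjusted p = 0.0580 with an estimated correlation). In these ribosomal lists 0 single genes passed in limma, where 6 and 9 had an unadjusted p under 0.05.

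The responses to prolonged and temporal induction were set side by side to see how far they overlapped. Of the 386 probe sets that changed after temporal induction, 355 changed the same way after prolonged induction, 256 up and 99 down, and 0 went opposite ways. AT5G22430, AT1G68875, AT4G23680 and AT5G64120 were leading rises, and AT3G28550 a leading fall, of both. Independent lists of these sizes would share 10.2 rises and 3.69 falls, and unchanged groups simulated against the same control arrays shared 0.02 calls on average. Such groups have almost no calls, so the simulation does not show how many of the 355 the shared control arrays produce. Across probe sets the log2 fold changes correlated at r = 0.75, against 0.50 in the simulation, and 77.7% had the same sign, against 66.7%. Their covariance was 0.307, 0.213 above the simulated 0.0939. With each response set against a different control array, an alternative added after the results were seen, the covariance was 0.168 and 0.178. The correlation r was 0.31 and 0.33. Unchanged groups would here give values near 0 if the control arrays vary independently, so the simulated 0.50 is no reference for them. Both covariances lay above 0 and below the excess of 0.213, so part of that excess may come from the shared controls. Calls were not compared in this way. A constant difference between the control and induced lines would also give shared changes, and no induced-line group without inducer was measured to show it. Median centring left 225 shared calls, and leaving out temporal replicate 1 or 2 left 65 or 49.

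**Figure D3:**
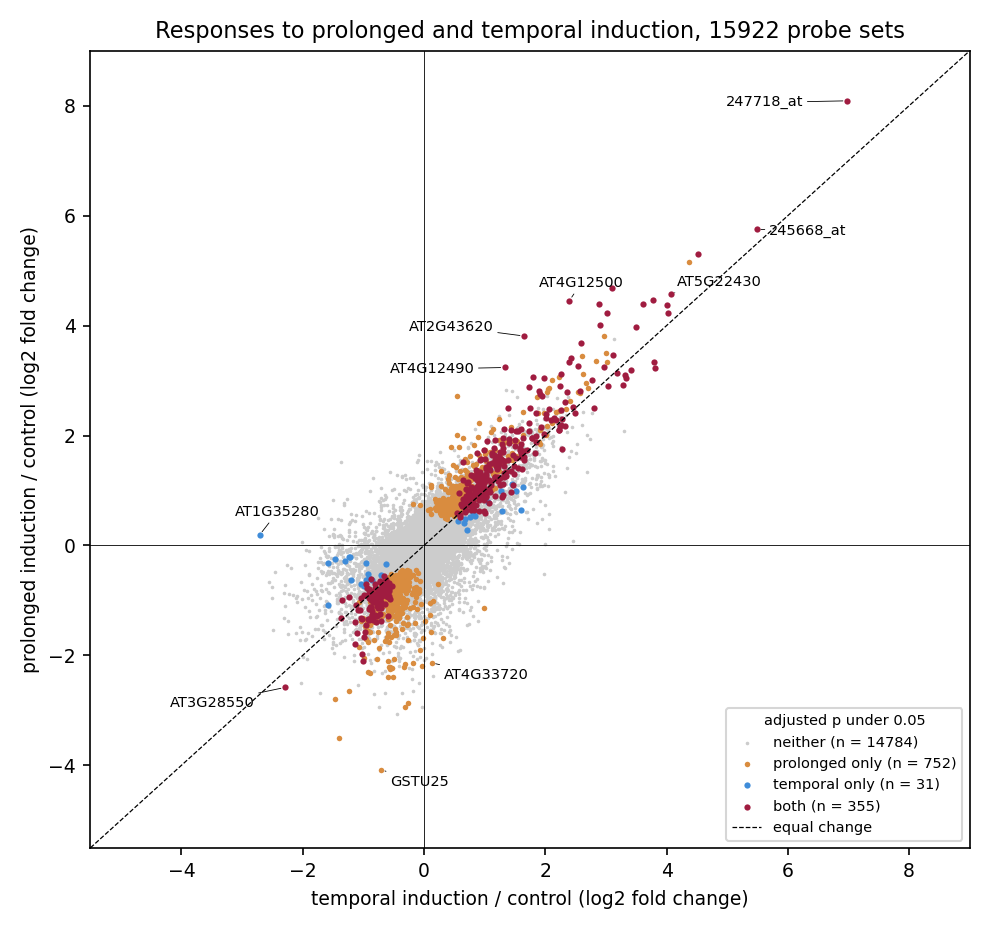
Log2 fold changes of 15922 probe sets against control after temporal (horizontal) and prolonged (vertical) induction, each comparing 2 arrays with 2; colours mark probe sets past an adjusted p of 0.05 in one comparison or in both, and the dashed line marks equal change. GSTU25 lies far below that line and AT4G12490 above it, with log2 fold changes of −4.08 and 3.24 after prolonged induction.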

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

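A test of the difference between the induced groups picked out 7 named genes whose change against the shared control differed between prolonged and temporal induction. The differences, prolonged minus temporal on the log2 scale, were 2.90 for AT1G35280, 2.16 for AT2G43620, 2.06 for AT4G12500, 1.90 for AT4G12490, −2.12 for OSM34, −2.26 for AT4G33720 and −3.37 for GSTU25. AT4G12490, AT4G12500 and AT2G43620 rose in both, by 3.24, 4.46 and 3.81 after prolonged and by 1.33, 2.40 and 1.65 after temporal induction, where AT2G43620 did not pass without temporal replicate 1 (adjusted p = 0.0596) or 2 (0.0835). GSTU25 fell by 4.08 after prolonged induction and did not pass after temporal induction (−0.71, adjusted p = 0.347). AT4G33720 fell by 2.13 after prolonged induction and had a log2 fold change of 0.13 after temporal induction. AT1G35280 fell by 2.71 after temporal induction only. OSM34 fell by 1.13 after prolonged induction (adjusted p = 0.0497), a call lost after median centring (0.0725), with no filter (0.0796), without the intensity trend (0.269), in the fit of 2 groups (0.0771), without control replicate 2 (0.201), without prolonged replicate 2 (0.233) and without either temporal array (0.0826 and 0.0814). It had a log2 fold change of 0.99 after temporal induction (adjusted p = 0.139). In the test of the difference, only AT4G12490 of these 7 passed without temporal replicate 1 or 2.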

How the results depend on the processing

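Of 121 single-gene results 105 were calls, of which 9 were kept under every alternative that gave a value (2 of these 9 had no value under 1 of them) and 96 were lost under at least 1, and 2 of the 121 changed sign; of 1788 single-gene values 1385 were unchanged in call and direction, 390 weaker, 7 stronger and 6 reversed. The cause was not tested. Without each array in turn, where the lone array of a group was assumed to vary like the other groups, the counts of probe sets were 633 to 897 (prolonged against control), 56 to 366 (temporal against control) and 1 to 18 (prolonged against temporal), those of fixed lists 1 to 4, 1 to 3 and 0 to 1, the shared calls 49 to 339 and the division genes 0 to 1. Without the intensity trend 47, 0 and 0 probe sets and 0 shared calls passed (main 1107, 386, 14 and 355). Median centring gave 249 after temporal induction and 225 shared calls, and the share of rises between the induced groups was 54.5% against 42.9%. The offset gave 22 and the fit of 2 groups 24 probe sets between the induced groups. Of the fixed lists, 4 in prolonged and 3 in temporal against control, 0 and 0 passed with an estimated correlation, 2 and 1 after quantile normalization, 2 and 1 after cyclic loess, and 1 in temporal against control without the intensity trend. The highest over the lowest median signal of the arrays was 1.11.

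Signs reversed for FTSZ2-1 after prolonged induction with quantile normalization (−0.00131) and cyclic loess (−0.000806), and without single arrays: its log2 fold change against control was −0.141 to 0.195 after prolonged and −0.226 to 0.110 after temporal induction. The direction of the list test reversed without single arrays for the plastid genome (medians −0.471 to 0.00750 after prolonged induction, −0.407 to 0.159 after temporal induction, −0.190 to 0.0484 between them), for class III peroxidases after temporal induction (−0.0819 to 0.0179; 0.0384 with the lowest 50% left out) and, between the induced groups, for the photosystem list (−0.243 to −0.0284; −0.0586 after cyclic loess) and the anther list (−0.292 to 0.300). With the lowest 50% left out, 4 of the 10 leading rises and 6 of the 10 leading falls of prolonged induction had no value. With the replicate block 1046, 374 and 17 probe sets passed, and 1 fixed list between the induced groups. Deviations of equally numbered arrays correlated at 0.012, 0.011 and −0.060, so these values show no pairing by replicate number. They cannot show whether equally numbered samples were handled together.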

Other observations

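Lists written after the leading genes were seen also held changes, but leading genes are among their members. The lipid transfer list holds AT1G66850, AT4G12490, AT4G12500 and AT5G62080. Of its 21 tested genes 3 had control signals not above 23.5. Those passed the filter only through higher induced signals, which favours a rise of the list. The class III peroxidase list holds AT5G64120, its only rise against control. Tests of these lists are therefore not separate from the leading genes. Of 21 lipid transfer protein genes 7 rose and 3 fell after prolonged induction (median 0.59, adjusted p = 0.00306; adjusted p = 0.0542 with an estimated correlation), AT1G48750 from 606 ± 47.9 to 1396 ± 180 and AT2G10940 in the other direction from 1744 ± 96.7 to 830.5 ± 83.1. After temporal induction 6 rose and 1 fell (median 0.18, adjusted p = 0.00160; adjusted p = 0.0976 with an estimated correlation). Of 34 class III peroxidase genes 1 rose and 5 fell after prolonged induction, AT5G17820 by 2.07 and AT4G26010 by 1.63 on the log2 scale (median −0.29, adjusted p = 0.00404; adjusted p = 0.0542 with an estimated correlation). After temporal induction 1 rose and the list did not pass (adjusted p = 0.821). Between the induced groups the peroxidase list was lower after prolonged induction (median −0.38, adjusted p = 2.75e-05; adjusted p = 0.0580 with an estimated correlation), where 0 of 34 passed in limma, 10 had an unadjusted p under 0.05 and 5 fell adjusted over the list alone. After temporal induction the root hair and root epidermis list had a median of −0.43 (adjusted p = 0.0315; adjusted p = 0.135 with an estimated correlation), and 0 of 5 passed in limma, where 1 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. That list call was lost without control replicate 1 (0.123) or temporal replicate 2 (0.135). Between the induced groups its median was −0.55 (adjusted p = 0.000741; adjusted p = 0.0598 with an estimated correlation), and 0 of 5 passed in limma, where 2 had an unadjusted p under 0.05 and 2 fell adjusted over the list alone. It was lost without prolonged replicate 1 (0.0703). Of 34 families with a common symbol stem 2, ATG and GSTU, passed after prolonged induction, 1, ATG, after temporal induction, and 0 with an estimated correlation (adjusted p = 0.872 and 0.937).

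Predictions for the anther and root lists and for neighbouring genes were written before their tests and after the leading genes were seen, and the cyclic loess test was chosen after its result was seen. Of 10 measured anther and tapetum genes 1, ATA27, rose after prolonged induction (list median 0.95, adjusted p = 0.00404; adjusted p = 0.112 with an estimated correlation) and 0 passed in limma after temporal induction, where 7 had an unadjusted p under 0.05 and 5 rose adjusted over the list alone (list median 1.47, adjusted p = 0.000423; adjusted p = 0.0976 with an estimated correlation). Without the leading genes the median of the other 9 was 0.80 after prolonged and 1.46 after temporal induction. The highest signals in any group were those of ATA27 (12.2, 103 and 72.4 in control, prolonged and temporal induction), AT3G52130 (36.9, 62.0 and 85.8) and AT5G48210 (31.4, 46.4 and 76.2), though signals of different probe sets do not compare abundance. Flower bud tissue in the induced seedlings could raise them, and so could expression in other parts of the seedling, which these values do not tell apart. A list of floral organ identity genes, also written after the leading genes were seen, had no tested member. AGL24 did not pass after temporal induction either. Its log2 fold change there was 1.18 to 1.94 over the alternatives, with an unadjusted p under 0.05 in limma. Of the 10, 2 are also in another list, 6 had control signals above 23.5 and 4 did not. Those 4 passed the filter on the mean of all arrays only through higher induced signals, which favours a rise of the list.

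Of 5 measured root hair and root epidermis genes 1, HRGP1 (AT3G54590), fell after prolonged induction, from 517 ± 30.5 to 272 ± 76.7 (5 fell adjusted over the list alone; median −1.14, adjusted p = 0.000310; adjusted p = 0.0542 with an estimated correlation). HRGP1 did not pass without control replicate 1 or prolonged replicate 1. Of the 3 root markers, EXPA7 and EXPA18 are also in the root hair list, so pooling the lists added only PYK10. None of the pooled genes was a leading gene, so leaving the leading genes out removed none. The 6 pooled genes had a median of −1.05 after prolonged induction, −0.42 after temporal induction and −0.46 between the 2 (camera p = 0.0262, 0.0892 and 0.0351 with an estimated correlation). A smaller share of root in the harvested tissue could lower them, and PYK10, the root marker with the highest signal, read 4333 ± 462, 3219 ± 850 and 3636 ± 54.5 in control, prolonged and temporal induction and did not pass. Fewer root hairs could give the same values, and the 2 were not told apart.

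Many probe sets separated both induced groups from control. A genetic block that differs between the lines might do this, since the labels give 2 Ler backgrounds. The highest number of prolonged induction calls in 50 neighbouring genes was 8, where shuffled gene orders gave up to 11 in 95% of cases. Only the 482 calls with 1 gene symbol and a place on a chromosome were counted. Line differences spread over the genome would form no such block, so the count cannot exclude them. Unequal scaling could also separate the groups. Of the 1107 calls of prolonged induction, though, 1046 were kept after cyclic loess, 1020 after quantile normalization and 852 after median centring. Of the 386 calls of temporal induction 373, 339 and 249 were kept, so whether part of them passed depended on scaling. Their size hardly did under median centring, which moves all fold changes of a comparison equally. The median log2 fold change over all probe sets went from −0.0017 to −0.0129. The construct and the background label differ together between control and induced groups, and prolonged induction also differs from control in the length and route of exposure to estradiol, so these effects were not separated.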
